A study of Gallus gallus with 24 samples.

How the data were processed

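MicroRNA levels were measured in total RNA from the ectoderm of the chick frontonasal ectodermal zone on 24 one-colour Cy3 Agilent arrays of a custom design, 4 arrays in each of 6 groups. The arrays lay on 3 slides of 8. Nothing in the labels says how many embryos went into a sample or whether the samples of a group were collected separately, so every p-value measures the spread between these samples.

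Per the file headers, each array file holds the output of Agilent Feature Extraction 9.5.1.1 with a miRNA extraction protocol, and its spot signals are intensities without scaling between arrays. The submitters' processing notes name Feature Extraction 10.1, and the labelling text describes a kit for amplified cRNA. The difference was not resolved. The deposited processed signal is an intensity with the background subtracted and a spatial trend removed within the array. Per the file headers, other columns hold flags of each spot (well above background, non-uniform, population outlier, saturated), coded as 0 or 1. The deposited table of values is in log2 units. It was recomputed here as the log2 median spot signal without background subtraction, quantile normalized over 14352 spots of 2191 probes on 24 arrays, and differed from that by at most 5e-04, the rounding of its 3 decimals. It served as an alternative only.

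The arrays carry 15132 non-control spots for 2481 probes, with a median of 6 spots per probe. The files name the probes by number and sequence and do not pair them with miRNA names, and the reference tables at hand hold none. The target of a probe was therefore read as the reverse complement of its sequence without the tail of 10 T and the labelling G. Targets ran from 14 to 29 nt. A probe was given a seed class where positions 2 to 8 of its target, counted from the 5′ end, equal any of 88 seeds of well-known miRNA families in a table written before any comparison. The fixed plan had called for named chicken miRNAs averaged over their probes, which the files do not allow, so each probe was tested by itself. A class says that a probe carries a seed. It does not say which gene was measured. Probes that differ by a base or in length may share signal, so counts of probes were not read as counts of miRNAs. The 290 probes outside the deposited table include variants of known miRNAs with changed bases.

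Spots with a non-uniformity or population outlier flag were left out. Each array was divided by the 75th percentile of its processed signal over the 362 probes detected on all arrays, relative to the median of these percentiles over the arrays. This rule applied because 25.6% of probe and array pairs were detected, where detection means that most spots of a probe were well above background. Scaled signals below 5.72 were raised to it (2.52 on the log2 scale), spots were averaged per probe after log2, and probes detected on at least 4 arrays were tested. These were 781 probes with 490 distinct seeds. Of them, 274 carried a listed seed, covering 66 of the 88, and 507 did not. No spot was saturated. Correlations between arrays of a group ran from 0.971 to 0.997. With 4 arrays per group, their number limits the precision.

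A linear model with 1 mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (tables read with version 1.17.8 of data.table), with empirical Bayes moderation (18 residual and 2.71 prior degrees of freedom). Its moderated test was two-sided, with Benjamini-Hochberg adjustment over the 781 probes and a threshold of 0.05. The comparisons were HH22 vs HH18, 5E1 vs 40-1A, SHH-N vs PBS, both control groups against HH22, and the 5E1 effect minus the SHH-N effect. The miR-199 probes and their mean were also tested by a two-sided exact permutation test over the 70 label orders of 4 against 4, whose smallest p is 0.0286. The relation between comparisons was measured across probes, with the group labels permuted within each comparison in 100 draws.

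Lists of miRNAs were matched to the probes by seed, and 16 of 20 had at least 3 tested probes. They were miR-199/miR-214, mesenchyme and smooth muscle, Hedgehog-linked, epithelial, neural, blood, hybridoma or B lymphoid, let-7, miR-17-92 with paralogs, miR-302/miR-367, miR-130/miR-301, miR-183/miR-96/miR-182, miR-99/miR-100/miR-125, miR-15/16, miR-34/miR-449 and miR-221/miR-222. Too few probes were left for skeletal and cardiac muscle (2), liver and gut (2), the Hox cluster (0) and miR-29 (0). Lists were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 16 lists. Camera compares a list with the other tested probes, and 507 of the tested probes carried no listed seed. A shift between probes with and without a listed seed therefore moves all lists. Some probes are in more than 1 list, such as miR-199 and miR-214 in both of theirs.

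The comparisons, tests, lists and naming rule were fixed before the data were examined. The rule named the miR-199/miR-214 probes, the 10 largest rises and falls past the threshold, or the smallest p where fewer than 5 passed, and 2 to 4 examples per list. For the control comparisons and the difference it named the 5 probes with the smallest p. Whole seed classes and probes sharing a sequence motif were described after their values were seen. For probes without a listed seed at most 2 rises and 2 falls are given per comparison.

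On simulated arrays of HH22 vs HH18 with 781 probes, the same fit and threshold recovered 80 of 100 probes with a log2 change of 1. They recovered 98 of 100 with a change of 2 and called 8 unchanged probes. Values were drawn independently, without brightness or slide differences, and the scaling, floor and filter were not run on them. These rates therefore describe the fit only and do not carry over to the real arrays. Alternatives were normexp background correction with an offset of 50, quantile normalization, the 75th percentile over all probes, no scaling, the deposited table, the summed gene signal, no filter, detection on all 24 arrays, the brightest probe of each seed, slide or replicate number as a block, only the arrays compared, a trended and robust fit, array weights, and leaving out each array in turn. A brightness covariate (the log2 scaling factor), only the probes of the deposited table, and the removal of dim arrays were added after seeing the data.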

Results

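Ectoderm of the frontonasal ectodermal zone, the facial signalling centre that expresses Sonic hedgehog (SHH) in the upper jaw primordium, was profiled for miRNAs in 6 groups of 4 arrays. Normal chick embryos were taken at HH18 (48 h of incubation) and HH22 (72 h). In the treated groups, all collected at HH22, hybridoma cells secreting the SHH-blocking antibody 5E1 or the control antibody 40-1A had been put into the neural tube at HH10, or a bead soaked in SHH-N (400 ng/ml), the active amino-terminal part of SHH, or a control bead had been implanted. The labels give more than 1 time for the beads, and call the control bead PBS in the sample titles and 0.1% albumin in the protocol. Brightness differed between groups. Scaling factors ran from 0.201 to 0.403 in HH18, 0.438 to 0.957 in HH22, 0.98 to 1.88 in 40-1A, 0.794 to 1.69 in 5E1, 0.48 to 1.12 in PBS and 1.67 to 2.61 in SHH-N. The number of probes detected per array ran from 422 to 536 in HH18 and from 509 to 811 in the other groups. Values are log2 scaled signals with SD (n = 4 arrays), and changes are log2 differences with the SE of the limma fit. Where a probe was not above background on any array of a group, the change is given as a lower bound against the lowest detected signal on each of those arrays. No fold is given where the other group was mostly not above background either.

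The comparison of HH22 with HH18 asks which miRNAs change in normal ectoderm across the onset of SHH expression. Probes with the seeds of miR-199, a family best known from mesenchyme and smooth muscle, were higher at HH22. The miR-199-5p-seed probe UCSF032_000559 (CCCAGUGUUCAGACUACCUGUUC) rose 4.50-fold, from 7.68 ± 0.68 to 9.85 ± 1.56 (change 2.17, SE 0.61, adjusted p = 0.0151). The miR-199-3p-seed probe UCSF032_000558 (ACAGUAGUCUGCACAUUGGUUA) rose 3.70-fold (change 1.89, SE 0.57, adjusted p = 0.0224). The second miR-199-5p-seed probe, UCSF032_000561 (CCCAGUGUUUAGACUACCUGUUC), rose by 2.15 (SE 0.60, adjusted p = 0.0152). Probes with the miR-214 seed, which shares a transcript with miR-199, rose by 1.92 (UCSF032_000605, ACAGCAGGCACAGACAGGCAG, SE 0.66, adjusted p = 0.0422) and 2.02 (UCSF032_000606, SE 0.69, adjusted p = 0.041). All 5 probes of the miR-199/miR-214 list passed, and 5 adjusted over the list alone. The family is named in the series title, so the list is not independent evidence of its direction. By camera the list rose (adjusted p = 0.00568), but adjusted p = 0.661 with an estimated correlation. The mean of the 3 miR-199 probes differed by 2.07 (exact permutation p = 0.0286, the smallest possible with n = 4; 0.129 after adjustment over 18 tests). Within the slides the difference was 1.00, 2.89 and 2.68, and 2.06 with slide as a block. Probes with the seeds of miR-143, miR-145 and miR-126, of mesenchyme and vessels, differed in the same comparison by a mean of 0.80 (SE 0.49, exact p = 0.314). The HH22 arrays did not lie together: UCSF032_000558 read 9.25 and 9.86 in replicates 1 and 2 and 7.35 and 6.65 in replicates 3 and 4. Leaving out HH18 replicate 1 ended the calls of UCSF032_000558 (adjusted p = 0.0809), UCSF032_000559 (0.058) and UCSF032_000561 (0.0547), as did HH22 replicate 1 (0.0711, 0.05 and 0.0536), and HH22 replicate 2 ended those of UCSF032_000558 (0.079) and UCSF032_000559 (0.0521). With array brightness as a covariate the changes were 1.81, 2.52 and 1.53 and did not pass (adjusted p = 0.155, 0.0677 and 0.243). A further 3 probes share 15 bases with the miR-199-3p target but are offset, so they carry no listed seed. UCSF032_000556 and UCSF032_000557 rose by 1.99 (adjusted p = 0.012) and 2.27 (0.00944). UCSF032_000560, above background on no HH18 array, was at least 2.35-fold higher (adjusted p = 0.00944). The calls of UCSF032_000557 and UCSF032_000560 held without any single array. Both turned below 0 with normexp correction, where the median over all probes was −1.

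**Figure D1:**
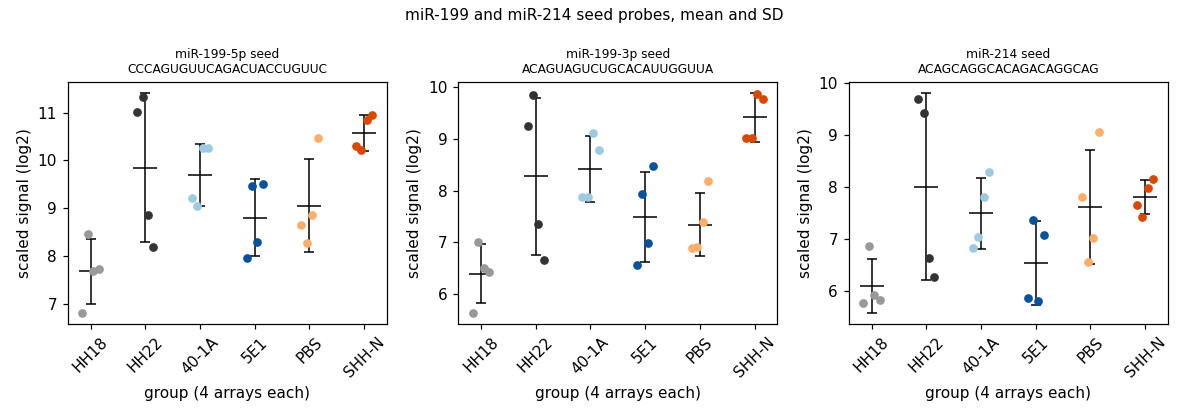
Log2 scaled signal of 1 miR-199-5p-seed, 1 miR-199-3p-seed and 1 miR-214-seed probe in the 6 groups; points are arrays (4 per group), bars the mean and SD. The miR-199-3p-seed probe UCSF032_000558 averaged 6.39 in HH18, 8.28 in HH22, 8.42 in 40-1A, 7.49 in 5E1, 7.34 in PBS and 9.42 in SHH-N, and the HH22 arrays fall into a high and a low pair.

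Between HH18 and HH22 the let-7 family, which marks developmental time, rose, and the miR-302 family of early embryonic cells fell. Of 28 probes with the let-7 seed, 20 rose and none fell (22 adjusted over the list alone), with a median change of 1.95. It turned to −0.74 with normexp background correction, where the median over all probes was −1. UCSF032_000002 (UGAGGUAGUAGGUUGUAUAGUU) rose by 1.98 (SE 0.21, adjusted p = 7.97e-07). UCSF032_000005 (UGAGGUAGUAGGUUGUGUGGUU), above background on 1 of 4 HH18 arrays, rose by 2.34 (SE 0.24, adjusted p = 7.07e-07). UCSF032_000020 (UGAGGUAGUAGUUUGUACAGU) was above background on no HH18 array and was at least 2.88-fold higher at HH22 (adjusted p = 4.82e-07). All 3 probes with the miR-302 seed fell, and 3 adjusted over the list alone, with a median below 0 under every alternative run. UCSF032_000769 (UAAGUGCUUCCAUGUUUCAGUGG) fell by 2.28 (SE 0.29, adjusted p = 7.71e-06). UCSF032_000775 read lower at HH22 (adjusted p = 8.94e-06), but it was above background on 1 HH18 array and on no HH22 array, so no fold is given. Within the slides the mean of the let-7-seed probes differed by 1.35, 1.78 and 1.49 (1.49 with slide as a block), and that of the miR-302-seed probes by −1.62, −1.26 and −1.27 (−1.45). Camera called let-7 up (adjusted p = 1.6e-17; adjusted p = 0.0854 with an estimated correlation) and miR-302/miR-367 down (adjusted p = 6.07e-05; adjusted p = 0.0327 with an estimated correlation, the only list of any comparison called both ways).

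**Figure D2:**
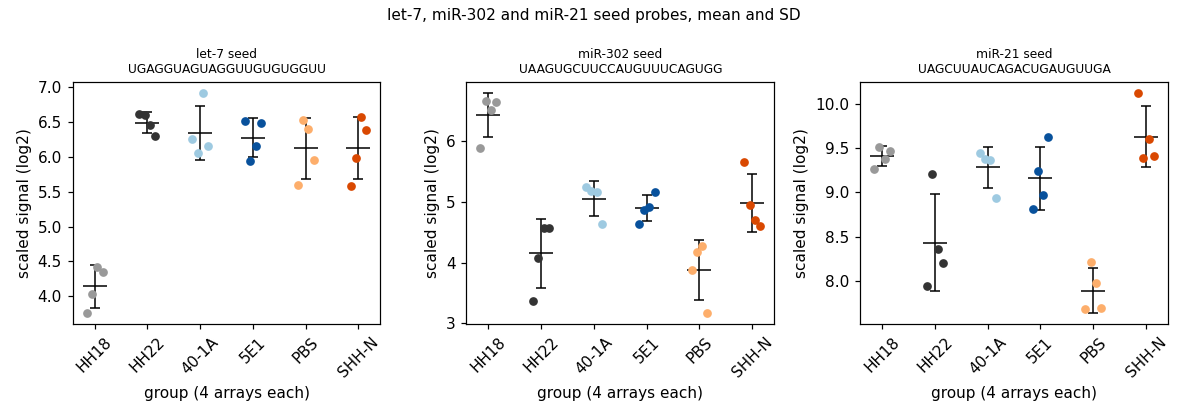
Log2 scaled signal of a let-7-seed, a miR-302-seed and a miR-21-seed probe in the 6 groups; points are arrays (4 per group), bars the mean and SD. The let-7-seed probe UCSF032_000005 averaged 4.14 in HH18 and 6.49 in HH22, while the miR-302-seed probe UCSF032_000769 averaged 6.43 and 4.15. The let-7 rise became −0.32 with normexp background correction, where the median change over all probes was −1.

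Smaller groups also moved with stage. Both miR-133-seed probes, of muscle, fell (UCSF032_000390, change −0.78, SE 0.20, adjusted p = 0.0113), although the median of the 2 became 0.43 without scaling. Of the 4 miR-125-seed probes, a family transcribed with let-7, 2 rose (UCSF032_000364, UCCCUGAGACCCUAACUCGUGA, change 0.56, SE 0.13, adjusted p = 0.00645). In the mesenchyme and smooth muscle list 8 of 36 probes rose and none fell (13 adjusted over the list alone), 5 of them the miR-199 and miR-214 probes; camera gave adjusted p = 0.001, and adjusted p = 0.661 with an estimated correlation. In the miR-17-92 list, of proliferating cells, 3 of 29 fell (2 adjusted over the list alone), all with the seed that miR-92 shares with miR-367 of the miR-302 cluster, so the list does not tell the clusters apart. UCSF032_000308 (UAUUGCACUCGUCCCGGCCUCC) fell by 0.55 (SE 0.18, adjusted p = 0.0363). UCSF032_000884 (AAUUGCACUUUAGCAAUGGUGA) read lower at HH22 (adjusted p = 0.000167). It was above background on 1 HH18 array and on no HH22 array, so no fold is given. For the list camera gave adjusted p = 0.00738, and adjusted p = 0.726 with an estimated correlation. None of 12 epithelial probes passed (miR-200, miR-203 and miR-205 seeds; 0 adjusted over the list alone, limma). In the Hedgehog-linked list 4 of 18 rose (4 adjusted over the list alone), those of miR-125 and miR-214. Of the other lists, blood had 2 rises and 1 fall among 15 probes (6 adjusted over the list alone), hybridoma or B lymphoid 2 rises among 14 (2), neural 1 fall among 19 (1), miR-99/miR-100/miR-125 2 rises among 7 (2) and miR-34/miR-449 2 rises among 8 (2). The lists miR-130/miR-301, miR-15/16, miR-183/miR-96/miR-182 and miR-221/miR-222 had 0 calls. In all, 179 of 781 probes passed in the limma fit, 86 up and 93 down, in 135 seeds, with a median change over all probes of −0.03. The count was 107 without HH22 replicate 3, 109 without HH18 replicate 1 and 114 without HH18 replicate 3; the split was 51 up and 120 down without HH22 replicate 1 and 100 up and 56 down without HH22 replicate 4. The count was 68 with the brightness covariate (34 up, 34 down), and 26 without the dim HH18 replicates 1 and 3. The split also moved with the processing: 18 up and 556 down with normexp correction (median over all probes −1), 480 up and 1 down without scaling (1.14), 132 up and 90 down with quantile normalization.

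The comparison of 5E1 with 40-1A asks which miRNAs depend on SHH signalling in the neural tube. Probes of mesenchymal and vessel families read lower after SHH was blocked, but no probe passed the test. The 3 probes with the seed of miR-126, an endothelial miRNA, had a median change of −1.90 (UCSF032_000365, UCGUACCGUGAGUAAUAAUGC, −2.01, SE 0.63, adjusted p = 0.243). The miR-143-seed probes had a median of −0.91 (UCSF032_000440, UGAGAUGAAGCACUGUAGCUCA, −1.23, SE 0.46, adjusted p = 0.266) and the miR-145-seed probes of −1.08. The miR-199-seed probes UCSF032_000558, UCSF032_000559 and UCSF032_000561 differed by −0.93, −0.89 and −0.50 (SE 0.57 to 0.61, adjusted p = 0.687, 0.762 and 0.939), and the miR-214-seed probe UCSF032_000605 by −0.96. Their miR-199 mean differed by −0.77 (exact permutation p = 0.2), and within the slides by −2.01, −0.27 and −0.41 (−0.74 with slide as a block). The mean of the miR-143, miR-145 and miR-126 seed classes, a set outside the fixed lists, differed by −1.30 (SE 0.49). It was lower in all 4 5E1 arrays than in any 40-1A array. Its exact permutation p of 0.0286 is unadjusted and the smallest possible. The same probes averaged −2.85, −0.56 and −0.39 within the slides. Among other classes of the mesenchyme list, the miR-22 median was −0.08. That of miR-27 lay between −0.29 and −0.004 over the settings run. The neural list went both ways (19 probes, median −0.06): miR-124 read higher by a median of 1.08, which became −0.37 with array weights, and the miR-9 probe UCSF032_000057 by 0.97 (SE 0.50, adjusted p = 0.486), while miR-129 and miR-7 read lower by medians of −0.44 and −0.34. Camera called 1 of 16 lists, mesenchyme and smooth muscle down (adjusted p = 2.05e-05; adjusted p = 0.896 with an estimated correlation), with 0 of 36 probes passing and 0 adjusted over the list alone. In the blood list 3 of 15 probes, those with the miR-126 seed, passed when adjusted over the list alone, and 0 over all probes. No probe passed in the other 14 lists, over all probes or adjusted over the list alone, including hybridoma or B lymphoid (14 probes, median −0.07). The limma fit called 0 of 781 probes, with 92 at an unadjusted p under 0.05, 5 higher and 87 lower. The median over all probes was −0.13 and lay between −0.17 (no scaling) and 0.08 (75th percentile over all probes) under the other scalings. The smallest adjusted p was 0.161, of UCSF032_000059 (UAAAGCUAGAGAACCGAAUGU, no listed seed, change 2.46, SE 0.55), which was above background on 1 of 4 control arrays. Leaving out 5E1 replicate 2 gave 41 calls, 1 up and 40 down, leaving out another 5E1 replicate gave 1, and array weights gave 267 (64 up, 203 down).

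The comparison of SHH-N with PBS beads asks which miRNAs respond to added SHH. After SHH-N the miR-199-3p-seed probe UCSF032_000558 was 4.22-fold higher than with PBS, at 9.42 ± 0.47 against 7.34 ± 0.61 (change 2.08, SE 0.57, adjusted p = 0.00644). It averaged 8.28 in untreated HH22 ectoderm and 8.42 in 40-1A, between the 2 bead groups, so part of the gap lies in low PBS values. No probe passed in PBS vs HH22, however. The miR-199-5p-seed probes UCSF032_000559 and UCSF032_000561 rose by 1.52 (SE 0.61, adjusted p = 0.0414) and 1.76 (SE 0.60, adjusted p = 0.0216). Neither miR-214-seed probe passed (UCSF032_000605, change 0.20, SE 0.66, adjusted p = 0.832). In the miR-199/miR-214 list 3 of 5 probes rose, and 3 adjusted over the list alone. The mean of the miR-199 probes differed by 1.78 (exact permutation p = 0.0286, n = 4; 0.129 after adjustment), by 1.69 and 0.93 within slides 1 and 2, and by 1.81 with slide as a block; slide 3 holds no PBS array. The miR-143, miR-145 and miR-126 seed classes averaged a change of 0.44 (SE 0.49, exact p = 0.171; 0.79 over their 17 probes), but they moved apart: 8 of 12 miR-143-seed probes rose with miR-199 (median 1.17, and −0.34 with normexp correction), while no miR-145-seed (median 0.07) or miR-126-seed probe (0.23) passed. Leaving out any replicate but PBS replicate 4 ended the call of UCSF032_000559 (adjusted p between 0.0507 and 0.113), leaving out SHH-N replicate 3 (adjusted p = 0.0657), SHH-N replicate 4 (0.064) or PBS replicate 1 (0.0816) that of UCSF032_000561, and no single replicate that of UCSF032_000558. With the brightness covariate the 3 changes were 2.00, 1.85 and 1.16 and did not pass (adjusted p = 0.132, 0.186 and 0.391). The offset miR-199-3p probes UCSF032_000556, UCSF032_000557 and UCSF032_000560 rose by 2.05, 2.04 and 2.35 (adjusted p = 0.00488, 0.0072 and 0.00272). Their calls held without any single array.

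Parts of several other families rose with SHH-N, but no list was called with an estimated correlation, and few of the calls were kept with the brightness covariate. All 6 miR-21-seed probes rose, with a median of 1.67 that became −0.41 with normexp correction and 0 without the filter. Over all probes the median was −0.48 with normexp correction and 0.93 without scaling. UCSF032_000142 (UAGCUUAUCAGACUGAUGUUGA) rose 3.34-fold, from 7.89 ± 0.25 to 9.63 ± 0.34 (change 1.74, SE 0.23, adjusted p = 5.62e-05). The mean of the miR-21-seed probes rose by 1.28 and 1.57 within slides 1 and 2 (1.45 with slide as a block). The largest rise was of UCSF032_000534 (AACUGGCCUACAAAGUCCCAGU), by 2.49 (SE 0.27, adjusted p = 6.66e-06), a call kept with the covariate; of the 4 probes with its miR-193 seed, 1 rose and 1 fell (median −0.03). Of 20 probes with the miR-15/16 seed, whose members restrain the cell cycle, 19 rose (19 adjusted over the list alone; median 1.12; UCSF032_000094, UAGCAGCACGUAAAUAUUGGCG, change 1.14, SE 0.21, adjusted p = 0.000633). In the miR-17-92 list, which promotes proliferation, 19 of 29 rose and 1 fell (22 adjusted over the list alone), among them UCSF032_000114 (UAAGGUGCAUCUAGUGCAGUUA, miR-18 seed, change 0.89, SE 0.15, adjusted p = 3e-04) and UCSF032_000121 (UGUGCAAAUCUAUGCAAAACUGA, miR-19 seed, change 1.22, SE 0.23, adjusted p = 0.000633). In the miR-130/miR-301 list 7 of 13 rose (7 adjusted over the list alone). In the mesenchyme and smooth muscle list 24 of 36 rose and none fell (24 adjusted over the list alone), including UCSF032_000175 (UUCACAGUGGCUAAGUUCUGC, miR-27 seed, change 1.09, SE 0.18, adjusted p = 3e-04) and UCSF032_000429 (CAGUGGUUUUACCCUAUGGUAG, miR-140-5p seed, a cartilage miRNA, change 1.18, SE 0.22, adjusted p = 0.000622); the median of the miR-27 class became −0.15 and that of miR-143 −0.34 with normexp correction. In the neural list 9 of 19 rose and 3 fell (12 adjusted over the list alone), with UCSF032_000624 (UUGUGCUUGAUCUAACCAUGUG, miR-218 seed) higher by 1.24 (SE 0.27, adjusted p = 0.00174) and UCSF032_000373 (CUUUUUGCGGUCUGGGCUUGCU, miR-129 seed) changed by −1.16 (SE 0.31, adjusted p = 0.0054); the miR-218 median became −0.41 with normexp correction and the miR-129 median 0.40 without scaling. With the brightness covariate, calls were kept for 2 of the 6 miR-21-seed probes (median 0.68), 0 of the miR-15/16 (0.33), miR-130/miR-301 (0.25) and neural lists, 1 of the miR-17-92 list and 5 of the mesenchyme and smooth muscle list, 4 of them with the miR-27 seed.

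In the epithelial list 1 probe rose (miR-200b seed) and 2 fell (0 adjusted over the list alone); those 2 carry the seed of miR-205, a marker of stratified epithelium, and UCSF032_000589 (UCCUUCAUUCCACCGGAGUCUG) fell by 0.55 (SE 0.21, adjusted p = 0.0312), although the miR-205 median rose above 0 with quantile normalization and without scaling. Of the 28 let-7-seed probes 27 did not pass and 1 fell. In the Hedgehog-linked list 5 of 18 rose (4 adjusted over the list alone), all with the miR-30 seed. The blood and miR-99/miR-100/miR-125 lists had 0 calls in limma. The remaining lists had these calls: hybridoma or B lymphoid 5 rises of 14 (4 adjusted over the list alone), miR-34/miR-449 2 rises and 3 falls of 8 (5), and 1 rise each in miR-302/miR-367, miR-183/miR-96/miR-182 and miR-221/miR-222 (1 in each). Camera called 6 lists up: miR-15/16 (adjusted p = 2.24e-08), mesenchyme and smooth muscle (6.78e-08), miR-17-92 (7.64e-07), miR-130/miR-301 (0.000675), neural (0.0195) and Hedgehog-linked (0.0218). None held with an estimated correlation, where adjusted p = 0.325 for the first 2 and 0.342 for the other 4. All probes with a listed seed had a median change of 0.48 and those without of −0.59. Camera alone therefore does not set these lists apart from listed seeds in general. Of all 274 probes with a listed seed 118 rose. That share was close to the neural list's, above the Hedgehog-linked list's and below those of the other 4. Among probes without a listed seed, 12 that share the motif GGCAGGGGA, singled out after their values were seen, all fell, with a median of −1.69 (UCSF032_002206, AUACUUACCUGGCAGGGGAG, change −1.85, SE 0.32, adjusted p = 0.000345). UCSF032_002206 differed by −0.91 on slide 1 and −2.59 on slide 2, which holds the dim PBS arrays, and did not pass without scaling (−0.44, adjusted p = 0.101) or with the brightness covariate (−0.78, adjusted p = 0.103).

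In all, 422 of 781 probes passed for SHH-N, 161 up and 261 down, in 285 seeds. Of 274 probes with a listed seed 118 rose and 16 fell, and of the 507 others 43 rose and 245 fell. Their median changes were 0.48 and −0.59, around −0.17 for all probes. That median became 0.93 without scaling, −0.48 with normexp correction, −0.27 with the summed gene signal, 0.14 with the 75th percentile over all probes, −0.01 in the deposited table and 0.00 with quantile normalization. Among the 507 probes without a listed seed, 39 overlap a probe that has 1, and 20 of these rose and 1 fell. The split was 167 up and 172 down with quantile normalization, 66.5% up among 334 with the 75th percentile over all probes, 477 and 1 without scaling, 49 and 258 with normexp correction and 135 and 128 in the deposited table. SHH-N arrays were all brighter than PBS arrays. The count fell to 48 (34 up, 14 down) with the brightness covariate and to 184 (68 up, 116 down) without the dim PBS replicates 1 and 4.

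**Figure D3:**
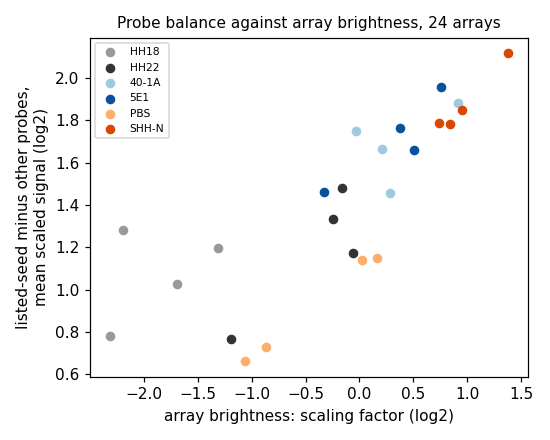
Mean log2 scaled signal of the 274 probes with a listed seed minus that of the 507 others (vertical axis) against the log2 scaling factor of each of the 24 arrays (horizontal axis), coloured by group. SHH-N arrays lie between 1.78 and 2.12 and PBS arrays between 0.66 and 1.15, and the SHH-N arrays are also the brighter ones. The 40-1A arrays lie between 1.46 and 1.88 and the 5E1 arrays between 1.46 and 1.96, so a high value is not particular to SHH-N.

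Both control groups were set against untreated HH22 ectoderm to measure the effect of the manipulation itself. With 40-1A, 5 of 781 probes passed, 2 up and 3 down (median over all probes −0.08). The split was 113 up and 6 down with the 75th percentile over all probes (0.18), 190 and 1 without scaling (0.50), 1 and 6 with the summed gene signal (−0.24), 52 and 46 with slide as a block and 107 and 131 with array weights, and no probe passed with normexp correction (−0.38), quantile normalization (0.03) or the deposited table. UCSF032_000832 (UCCAGCAUCAGUGAUUUUGUUGA, miR-338 seed, linked to neurons and bone) rose by 1.02 (SE 0.22, adjusted p = 0.0321), and UCSF032_000624 (miR-218 seed, expressed in motor neurons) by 1.17 (SE 0.27, adjusted p = 0.0462); with normexp correction these became −0.31 and −0.04. The 3 others have no listed seed and fell, UCSF032_001677 (AAAUCUACCUGCCUCUGCCU) by 1.86 (SE 0.34, adjusted p = 0.014) and UCSF032_000977 by 1.74 (SE 0.35, adjusted p = 0.0203). No call was left without 40-1A replicate 1, HH22 replicate 1 or HH22 replicate 3; 142 were made without HH22 replicate 2, 11 without 40-1A replicate 3, 3 without 40-1A replicate 4 and 1 without 40-1A replicate 2. Camera called 10 lists up, led by miR-17-92 (adjusted p = 6.23e-06), miR-15/16 (1.56e-05) and epithelial (5.18e-05), each with adjusted p = 0.357 with an estimated correlation, where none of the 10 was called. Adjusted over the list alone, 9 of 20 miR-15/16 and 5 of 12 epithelial probes passed. Probes with a listed seed had a median change of 0.30 and the others of −0.29, a gap that moves lists up in camera. With PBS beads 0 probes passed in limma, 43 had an unadjusted p under 0.05 (3 higher, 40 lower), and the smallest adjusted p was 0.465, that of the 5 named probes, among them UCSF032_000048 (UGGAAGACUAGUGAUUUUGUUG, miR-7 seed, change −1.08, SE 0.31) and UCSF032_000114 (miR-18 seed, change −0.50, SE 0.15). Camera called 7 lists down, led by neural (adjusted p = 4.43e-06, with 4 of 19 probes passing adjusted over the list alone). None was called with an estimated correlation, where adjusted p = 0.094 for neural and 0.514 for the other 6. Probes with a listed seed had a median change of −0.22 and the others of 0.04, a gap that moves lists down in camera.

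Whether blocking and adding SHH moved a probe differently was tested as the 5E1 effect minus the SHH-N effect. It passed for 126 of 781 probes, 96 below 0 and 30 above, and all 65 with a listed seed were below 0. The split was 75 above and 70 below with the summed gene signal (median over all probes 0.23, against 0.08), 20 and 24 with normexp correction (0.53), 1 and 410 without scaling (−1.10), 88 and 169 with slide as a block and 155 and 190 with array weights. The miR-193-seed probe UCSF032_000534 differed by −2.88 (SE 0.38, adjusted p = 0.000176) and the miR-27-seed probe UCSF032_000175 by −1.55 (SE 0.26, adjusted p = 0.00185). For miR-199 the difference was −3.01 for UCSF032_000558 (SE 0.81, adjusted p = 0.0197), while UCSF032_000559 (−2.41, SE 0.86, adjusted p = 0.0606) and UCSF032_000561 (−2.26, SE 0.86, adjusted p = 0.0758) passed only adjusted over the list alone, where 3 of 5 passed. In the mesenchyme and smooth muscle list 14 of 36 were below 0 (26 adjusted over the list alone; camera adjusted p = 1.06e-11, and adjusted p = 0.182 with an estimated correlation), among them the miR-143-seed probe UCSF032_000440 (−2.42, SE 0.65, adjusted p = 0.0197). Camera called 6 lists below 0 and none with an estimated correlation. Probes with a listed seed had a median of −0.645 and the others of 0.393, a gap that moves lists below 0 in camera. The count was 57 to 79 without 5E1 replicate 1 (57) or 3 (59), 40-1A replicate 1 (64) or 2 (72), SHH-N replicate 1 (79) or 3 (60), or PBS replicate 1 (76) or 4 (74), and 3 with the brightness covariate.

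Across the 781 probes, which are not independent replicates, the changes of the 3 main comparisons were correlated in pairs. Stage and 5E1 effects had r = −0.398 and rho = −0.385 (permutation p = 0.25, adjusted 0.74), stage and SHH-N effects r = −0.011 and rho = −0.099 (permutation p = 0.99, adjusted 0.99), and 5E1 and SHH-N effects r = 0.184 and rho = 0.159 (permutation p = 0.69, adjusted 0.99). Stage and SHH-N shared 104 called probes, 13 up in both (17.7 expected from the counts), 43 down in both (31.1), 38 up at HH22 and down with SHH-N (28.7) and 10 the reverse (19.2). UCSF032_000534 rose in both (1.31 and 2.49), while the medians over all 4 probes with its miR-193 seed, itself included, were −0.01 and −0.03. The miR-302-seed probe UCSF032_000769 fell by 2.28 with stage and rose by 1.11 with SHH-N (adjusted p = 0.00488), and the miR-21-seed probe UCSF032_000142 fell by 0.98 (adjusted p = 0.00692) and rose by 1.74.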

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

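Chosen after the result was seen were the tests of brightness and slide for the SHH-N pattern, of near-identical let-7 probes, and of miR-199 against the other mesenchymal classes. In 4 of 126 groups of named probes, and 1 of 12 groups of array measures, 1 array lay further from the others than Dixon's 95% limit for n = 4; chance gives about 1 in 20 groups, so these counts are within what chance gives. HH18 replicate 4 had 536 probes detected, against 422 to 441 in the other 3. UCSF032_000605 (miR-214 seed) read 6.86 in HH18 replicate 2, against 5.77 to 5.91. UCSF032_002184 read 5.68 (others 4.84 to 4.94) and UCSF032_000854 4.32 (others 3.41 to 3.55) in HH22 replicate 1, the dimmest of its group. UCSF032_001677 read 3.82 in PBS replicate 3, against 4.84 to 4.87.

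The 5E1 and SHH-N effects differed in the test of the difference for 126 probes, among them UCSF032_000534 (−2.88), UCSF032_000175 (−1.55), UCSF032_000832 (−1.82), UCSF032_002459 (−1.89) and UCSF032_000326 (−1.83). Of 100 draws of other splits within both comparisons, the real one included, 3 gave as many, under the bound of 0.05 set beforehand. However, 1 other split gave 175, and 100 draws place so small a share only loosely, so chance is not excluded.

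Every split of the 8 arrays into 4 and 4 was tried. For HH22 vs HH18 only the real one of the 35 gave as many calls (179, at most 74 in the others). The same held for SHH-N vs PBS (1 of 35, 422 calls, at most 33 in the others), which argues against chance for both. The real splits also had the widest gaps in log2 scaling factor (1.46 and 1.41), and those with 74 and 33 calls had 1.40 and 1.13. Other splits with gaps of 0.961 and 1.07 gave 0 calls. The counts thus do not separate a group effect from brightness. For 5E1 vs 40-1A and PBS vs HH22 the real count was 0, which all 35 of 35 splits reach whatever the data, so the splits decide nothing about chance there; the highest others were 37 and 152. For 40-1A vs HH22, 3 of 35 gave at least the real 5, the highest 127, and chance is not excluded. Such counts, many times the real ones, point to a structure of the samples. The splits with 127 and 152 calls set 3 arrays of slide 2 and 1 of slide 3 against arrays of slides 1 and 3, and with slide as a block the real comparisons gave 98 and 2 calls.

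The first pattern is the broad SHH-N response, in which probes with a listed seed rose relative to the others by 0.964 (95% interval 0.626 to 1.3) while SHH-N arrays were all brighter. With the scaling factor as a covariate a difference of 0.424 (0.122 to 0.726) remained. This argues against 1 linear brightness effect shared by all groups as the whole cause. Scaling factors of SHH-N (1.67 to 2.61) and PBS (0.48 to 1.12) do not overlap, so a brightness effect of another shape is not excluded. Slide as the whole cause is argued against by 0.965 (0.619 to 1.31) with slide as a block and 0.638 and 1.09 within slides 1 and 2. The fall from 0.964 to 0.424 leaves brightness as a candidate explanation for part or all of this pattern. The count of calls fell from 422 to 48 with the same covariate, which follows the groups and so also widens the errors. More RNA, or better RNA, in the SHH-N samples might give the same pattern and was not tested, since the labels give no amount. Listed-seed probes minus the others averaged 1.78 to 2.12 in SHH-N arrays, but also 1.46 to 1.88 in 40-1A and 1.46 to 1.96 in 5E1 arrays. The brightest 40-1A and 5E1 arrays (scaling factors 1.885 and 1.694) had 1.88 and 1.96, so a high value is not particular to SHH-N. A response to SHH-N stays open as a hypothesis.

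The second pattern is the stage shift of let-7 up and miR-302 down. A linear brightness effect as its whole cause is argued against by a difference between the families of 2.63 (95% interval 1.87 to 3.4) with the covariate, against 2.98 without. HH18 and HH22 arrays do not overlap in scaling factor either, so a brightness effect of another shape is not excluded. Shared signal between near-identical let-7 probes cannot be told apart from a rise of several let-7 genes: probes 1 base away from a let-7-seed probe and outside the deposited table rose by a median of 1.13 (10 of 21 called), those inside it by 1.93 (12 of 13 called), between the bounds set for each reading. The number of let-7 miRNAs that rose is therefore unknown. A change with developmental stage may account for the opposite movement of the families, as a hypothesis.

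The third pattern is the movement of miR-199 with seeds of mesenchyme and vessels. Within groups, across 24 arrays, the miR-199 mean correlated with that of the miR-143, miR-145 and miR-126 classes (r = 0.882, rho = 0.878, permutation p = 3e-05, adjusted over 5 relations 0.00015; 0.863 without the 2 arrays farthest out, 0.883 with slide removed), but not with epithelial (r = −0.359, permutation p = 0.224) or neural seeds (r = −0.068) or brightness (r = 0.045), so a varying share of mesenchyme between dissections is a candidate explanation for the spread within groups. As the whole cause of the SHH-N rise it cannot be told apart from a change of miR-199 itself: the miR-199 rise exceeded the mean of the other 9 classes of the mesenchyme list by 1.25 (SE 0.446) and 6 of them by more than 2 SE, miR-214 by 1.58 (SE 0.385) and miR-145 by 1.71 (SE 0.328) among them and miR-143 the least (0.734, SE 0.348), but not miR-140-5p (0.601, SE 0.601), miR-22 (0.812, SE 0.718) or miR-27 (0.998, SE 0.602). Given the 3 marker classes, miR-199 still differed by 1.22 (95% interval 0.578 to 1.86) with stage and 1.31 (0.7 to 1.93) with SHH-N, and by 0.61 (−0.0999 to 1.32) with 5E1, where the markers differed by −1.3. Whether miR-199 in ectoderm cells, or the mesenchyme left on them, differs with SHH remains open.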

How the results depend on the processing

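Signal over background limits these results: 362 of 2481 probes were detected on all arrays, and the dimmest arrays were the 4 of HH18, then HH22 replicate 1 and PBS replicate 1. The brightness covariate, the deposited-table probes and the removal of dim arrays were chosen after seeing the data. The alternative of all named miRNAs of all species was not run, since the files hold no names. The cause was not tested for any change below, except where the construction of the alternative shows it.

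Of the counts of probes called, HH22 vs HH18 (179) became 574 with normexp background, where the offset of 50 is divided by the small scaling factors of dim arrays, 481 without scaling, where brightness stays in the values, 498 with no filter (2481 probes tested), 41 with detection on all arrays (362 tested), 273 with slide as a block, 56 with only the arrays compared (fewer degrees of freedom), 68 with the brightness covariate and 26 without HH18 replicates 1 and 3. 5E1 vs 40-1A (0) became 1 without scaling and 267 with array weights. SHH-N vs PBS (422) became 263 in the deposited table, 276 with no filter, 218 with detection on all arrays, 271 with the brightest probe of each seed (490 tested), 48 with the covariate and 184 without PBS replicates 1 and 4. 40-1A vs HH22 (5) became 0 with normexp, quantile normalization, the deposited table, no filter, detection on all arrays and only the arrays compared, 119 with the 75th percentile over all probes, 191 without scaling, 98 with slide as a block and 238 with array weights. PBS vs HH22 (0) became 2 with slide as a block and 1 with array weights. The 5E1 effect minus the SHH-N effect (126) became 44 with normexp, 411 without scaling, 39 with no filter, 50 with the brightest probe, 257 with slide as a block, 345 with array weights and 3 with the covariate. With single arrays left out the counts ran from 107 to 183, 0 to 41 (without 5E1 replicate 2), 309 to 410, 0 to 142 (without HH22 replicate 2), 0 to 0 and 57 to 145.

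The miR-199 mean kept its direction under every alternative run. The unadjusted exact p of 0.0286 for stage (2.07) and SHH-N (1.78), already 0.129 after adjustment, rose above 0.05. For stage it did so with normexp (0.62), detection on all arrays or the brightest probe (2.03 in both), or without HH18 replicates 1 and 3 (1.78), and for SHH-N with normexp (1.25), the deposited table (1.33), or without PBS replicates 1 and 4 (1.95); the last of each leaves 4 against 2 arrays, where no exact p under 0.05 is possible. With single arrays left out it ran from 1.67 to 2.57, −1.08 to −0.49 and 1.57 to 2.10. The exact p stayed at 0.0286 without any of the HH22 arrays and without PBS replicate 2, 3 or 4, and rose to 0.0571 or 0.0857 without any of the HH18 or SHH-N arrays or PBS replicate 1.

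Lists called numbered 5 for stage, 1 without scaling, 0 with the brightest probe and 8 with the covariate, and 6 for SHH-N, 3 without scaling. For 5E1 (1) they numbered 8 with normexp, 5 with no filter, 3 with quantile normalization, the deposited table and detection on all arrays, 2 without scaling, with the summed signal, slide block, replicate block and array weights, and 0 with the brightest probe. Left-out arrays gave 4 to 6, 6 to 7 and 1 to 4. Correlations of stage with SHH-N effects (−0.011) turned to 0.244 with normexp, 0.0201 with the percentile over all probes, 0.221 without scaling, 0.0146 in the deposited table, 0.069 with detection on all arrays and 0.0192 with slide as a block, and 5E1 with SHH-N (0.184) to −0.163 with normexp and −0.011 with detection on all arrays. With arrays left out they ran from −0.467 to −0.214 (stage with 5E1), −0.0985 to 0.103 and 0.0383 to 0.284. Replicates 1, 2 and 3 of HH18, HH22, 5E1 and 40-1A lay on slides 3, 2 and 1, so their numbers follow the slide, but 1 pair of each main comparison correlated below 0 (−0.219, −0.414 and −0.238) and 2, 2 and 3 of 4 samples fitted best with their own number, so the numbers were not taken to pair the samples. The replicate block gave 189, 0, 434, 6, 0 and 138 calls.

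Named probes turned direction as follows. With normexp at HH22: UCSF032_000561 −0.0745, UCSF032_000020 −0.58, UCSF032_002399 −0.68, UCSF032_002403 −0.64, UCSF032_000005 −0.32, UCSF032_000021 −0.81, UCSF032_000010 −0.52, UCSF032_000557 −0.10, UCSF032_002398 −0.59, UCSF032_002415 −0.29 and UCSF032_000560 −0.70. With normexp for SHH-N: UCSF032_000605 −0.0743, UCSF032_000606 −0.10 and UCSF032_002424 −0.28; for 40-1A vs HH22, UCSF032_000832 −0.31 and UCSF032_000624 −0.0399; for the difference, UCSF032_000832 0.40. Without scaling at HH22: UCSF032_000854 0.0836, UCSF032_000510 0.0778, UCSF032_000855 0.10 and UCSF032_001471 0.15. With the covariate: UCSF032_000855 0.041 and UCSF032_001471 0.0166. With array weights for 5E1: UCSF032_000561 0.14. For SHH-N with single arrays left out, UCSF032_000605 ran from −0.15 to 0.68 and UCSF032_000606 from −0.15 to 0.69, below 0 without PBS replicate 2 or 3.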

Other observations

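The probes, the motif and the slide correlation of this part were chosen after the values were seen; the comparisons with HH22 were planned. MiR-21-seed probe UCSF032_000142 stood at 8.43 ± 0.55 in HH22, 9.41 ± 0.11 in HH18, 9.28 ± 0.23 in 40-1A and 7.89 ± 0.25 in PBS (SD, n = 4 arrays), so the 2 control groups lay on either side of untreated ectoderm of their stage. Its difference from HH22 was 0.85 in 40-1A (SE 0.23, adjusted p = 0.0704) and −0.54 in PBS (SE 0.23, adjusted p = 0.838). MiR-126-seed probe UCSF032_000365, of endothelium, varied most in untreated HH22 ectoderm (6.44 ± 1.70) and stood at 7.15 ± 0.96 in 40-1A, 5.14 ± 0.78 in 5E1, 5.59 ± 0.52 in PBS and 5.72 ± 0.32 in SHH-N.

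The probes with the motif GGCAGGGGA had group means from 10.34 to 17.17 and did not pass in HH22 vs HH18 (0 of 12, median 0.28) or 5E1 vs 40-1A (0 of 12, median 0.05). No miRNA family was assigned to them, and whether they measure a miRNA at all was not tested.

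Deviations of arrays from their group mean correlated by a median of 0.347 between arrays of different groups on 1 slide (77 pairs) and −0.178 between slides (163 pairs), so arrays of a slide shared part of their deviation.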
